A study of Mus musculus with 14 samples.

How the data were processed

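The deposited table holds 45802 features in 14 libraries from mouse cortical cultures, sequenced as paired-end reads of 100 bases, per the labels' protocols. The values are log2 signals as deposited by the authors. Base 2 was checked on the values: antilogged and multiplied by exon length in kilobases they sum to 1180000 to 1270000 per library, against 8360000 to 9080000 with base e. The sorted values of the libraries share a median of 2.19 and a maximum of 12.0, as quantile normalisation leaves them. The build was GRCm38.p6, per the submitters' processing notes. The aligner, counter and annotation are not given in the sources used here. Of the features, 27674 had no value in any library and 18128 had a value in at least 1. Because quantile normalisation replaces each library's own distribution, whole reads could not be recovered, read depth is unknown, and a change in total RNA would not be seen.

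Columns were assigned to samples by the column name given in each label. Features were ranked by mean over all libraries, with missing values set to the table minimum for this ranking only, and the lowest 40% were dropped. This left 10877 genes with 0 missing values. Date-like names stood in place of 27 symbols and were not named. One linear model with a mean per group was fitted to all libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a variance trend. Two-sided p-values were adjusted by Benjamini-Hochberg within each of 7 comparisons, and an adjusted p under 0.05 was called. The series design states biological replicates, without saying what was replicated, so p-values measure the spread between these samples.

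Gene lists, 20 in number and fixed before the data were examined, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Mitochondrially encoded mRNAs and endothelial and mural markers had 0 tested genes, and the inflammatory and microglia lists had 1 each. Named genes followed a rule fixed at the same time: 7 index genes in every comparison, the largest changes per list (up to 10 in the activity lists and 4 in the others), and the 10 highest and 10 lowest called genes whose libraries do not overlap, without predicted gene models. Where no gene was called, the rule takes the 5 smallest p-values, of which 1 gene is not reported here. Nfil3, Txnip, Gfap, Ptgs2 and Arrdc4 were named after their values were seen. Positions were taken from RefSeq genes of the same build.

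The procedure was tested on simulated data with 10877 genes and 200 changed. For NMP peptides against DMSO it recovered 62.4%, 96.4% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale, and 4.12% of its calls were false. For NMP peptides against PK-cleaved NMP peptides it recovered 69%, 97.3% and 100%, with 4.73% false. Simulated noise was independent between genes and did not carry the shared deviations seen between libraries. The 200 changed genes were drawn at random from all genes, whose median SE in NMP peptides against DMSO was 0.115. Several activity genes had a larger SE there, such as 0.379 for Arc and 0.287 for Egr1, while Sik1 had 0.09. With fewer genes changed than 200, the adjusted threshold is also stricter. The recovered shares therefore do not describe the activity genes in the real comparisons.

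Whether replicate numbers pair libraries was checked by the correlation across genes of deviations from the group means. Deviations sum to 0 within a group, so the pairs of 2 groups are not independent of each other. Numbers were taken to pair 2 groups where at least 3 pairs each correlated over 0.1. This held for NMP peptides and PK-cleaved NMP peptides (0.51, 0.499 and 0.613), as a property of the data that the labels do not state. It did not hold for NMP peptides with NMP peptides plus APV or for bicuculline with NMP peptides. Comparisons with DMSO have 2 pairs and could not meet the rule. Their pairs correlated at 0.542 and 0.169 for bicuculline and 0.305 and 0.349 for NMP peptides plus APV. They correlated at -0.341 and -0.48 for NMP peptides and -0.449 and -0.413 for PK-cleaved NMP peptides.

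The alternatives were no filter, dropping 60%, centring on the median, a replicate block, fitting only the compared groups, no variance trend, array weights and leaving out each library. The alternatives for linear values, counts and several rows per gene did not apply. Added after seeing the data were residual principal components as covariates, leaving out the 4 libraries with the highest Gfap, a replicate block over the paired groups alone, and following the bicuculline genes in other comparisons.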

Results

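RNA was measured by sequencing of ribosome-depleted libraries from primary mouse cortical neuron cultures after 12 days in vitro, each treated for 1 h. The 14 libraries fell into 5 groups. The control group received 1% DMSO and had 2 libraries. A DMSO content is given for this group only in the sample information used here, so comparisons with it may also differ in solvent. The other groups had 3 libraries each and received 20 µM bicuculline, a GABA-A receptor blocker that raises network activity, peptides derived from the neuronal membrane proteasome (NMP peptides) at 4% by volume, the same preparation cleaved with proteinase K (PK-cleaved NMP peptides), or NMP peptides together with 100 µM APV, an NMDA receptor antagonist. Between 15824 and 16231 features had a value in a library, and 10877 genes were tested. Values are quantile-normalised log2 signals, and the read depth behind them is unknown. Gene positions are on GRCm38.

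Bicuculline raised immediate-early and other activity-regulated genes within 1 h. Npas4, a neuronal activity-dependent transcription factor (chromosome 19, 4984353 to 5003439), rose from 1.31 ± 0.70 (SD, n = 2) in DMSO to 5.64 ± 0.49 (SD, n = 3), a log2 fold change of 4.33 (SE 0.31) or 20.1-fold. Arc, which encodes a cytoskeleton-associated synaptic protein (chromosome 15, 74669081 to 74672570), rose 17.7-fold, and Fos, a subunit of the AP-1 transcription factor (chromosome 12, 85473890 to 85477274), rose 10.4-fold, from 4.32 ± 0.41 to 7.70 ± 0.38. Fosb, Egr4 and Junb rose by 3.91, 3.39 and 3.34 on the log2 scale. The limma test called 51 genes higher and 0 lower at an adjusted p under 0.05. In all 51 the bicuculline libraries lay above the DMSO libraries, which the selection of called genes makes likely and which adds no support. Over all tested genes the groups did not overlap, in either direction, in 17.8%, where chance gives 20%.

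Of 20 tested immediate-early transcription factors, 15 rose and 0 fell (18 higher when adjusted over the list alone), with a median log2 fold change of 2.28. Besides the genes above, Klf4 (log2 fold change 3.13, SE 0.30), Egr2 (3.03, SE 0.32), Nr4a1 (2.95, SE 0.30) and Egr1 (2.34, SE 0.29) were among them. Of 24 activity-regulated effectors, 11 rose and 0 fell (19 higher adjusted over the list alone). These included Gadd45b (9.32-fold), Btg2 (9.1-fold), Rgs2, a regulator of G-protein signalling (2.68-fold), and the kinase gene Sik1 (2.05-fold). Of 11 MAP kinase feedback regulators, 4 rose: the phosphatase genes Dusp1 (6.02-fold), Dusp6 (3.35-fold) and Dusp5 (2.75-fold), and Errfi1 (1.99-fold). Bdnf, which encodes a neurotrophin, had a log2 fold change of 1.42 (SE 0.38) that missed the threshold (limma adjusted p = 0.307). The heat shock chaperone list held 1 called gene, Dnajb1 (1.96-fold). All 3 activity-related lists also passed with an estimated correlation (adjusted p = 0.000434, 0.00118 and 0.00331). The count of called genes was 27 when only these groups were fitted and 30 without DMSO replicate 3.

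NMP peptides were compared with DMSO to ask whether the peptides change mRNA levels. Npas4 was 4.24-fold higher than in DMSO (3.39 ± 0.44, SD, n = 3; log2 fold change 2.08, SE 0.31) and Fos was 3.67-fold higher (log2 fold change 1.88, SE 0.28), both with a limma adjusted p of 0.0455. These were the 2 genes called, and 220 genes had an unadjusted p under 0.05. Nr4a1 had a log2 fold change of 1.88 (SE 0.30) and lay just outside the threshold (adjusted p = 0.052). Arc (1.64, SE 0.38), Egr4 (1.47, SE 0.37), Egr1 (1.16, SE 0.29) and Bdnf (0.64, SE 0.38) were not called. Adjusted over the list alone, 13 of 20 immediate-early transcription factors were higher and 1 was lower, and 10 of 24 activity-regulated effectors were higher. As lists, the immediate-early factors passed with an estimated correlation (adjusted p = 0.0101) and the effectors did not (adjusted p = 0.0595 with an estimated correlation). Without the 4 libraries with the highest Gfap the immediate-early list did not pass with an estimated correlation either. That fit keeps 1 DMSO library, so the smaller number of libraries alone could give this. The count was 0 without filtering, with the stricter filter, with only these groups in the fit, without the variance trend, with array weights, and without NMP peptides replicate 1 or 2. It was 6 with median centring and 10 without NMP peptides replicate 3, with Npas4 and Fos among the called genes in both. Without DMSO replicate 2 or without DMSO replicate 3, fits that keep 1 DMSO library, Npas4 and Fos were not both called.

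Proteinase K cleavage of the peptides gave a second control, with 3 libraries on each side. Intact NMP peptides gave 9 genes higher and 0 lower than the cleaved preparation: Npas4 (5.5-fold), Fosb (5.31-fold), Nr4a1 (3.84-fold), Fos (3.83-fold), Klf4 (3.63-fold), Junb (3.46-fold), Btg2 (2.33-fold), Sik1 (1.55-fold) and Ppp1r10, a regulatory subunit of protein phosphatase 1 (1.31-fold). Of the 20 immediate-early factors 6 rose (14 higher and 1 lower adjusted over the list alone). Of the 24 effectors 2 rose (10 adjusted over the list alone). The immediate-early list passed with an estimated correlation (adjusted p = 0.0106) and the effector list did not (adjusted p = 0.0596 with an estimated correlation). Same-numbered libraries of these groups deviated together. With the replicate block over these groups and all 14 libraries in the fit, 11 genes were higher and 0 lower, the 9 above together with Dusp1 and Dusp6. With the block and only these groups in the fit, 24 were higher and 1 lower, 8 of the 9 among them. Excitatory neuron markers had a median log2 fold change of -0.11 (adjusted p = 0.0138, and 0.527 with an estimated correlation). The count was 4 without filtering, 2 without NMP peptides replicate 1, 1 without NMP peptides replicate 2, 1 without PK-cleaved NMP peptides replicate 2 and 2 without PK-cleaved NMP peptides replicate 3.

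PK-cleaved NMP peptides against DMSO gave 0 called genes with limma, and 114 genes had an unadjusted p under 0.05. The log2 fold change was -0.38 (SE 0.31) for Npas4, -0.06 (SE 0.28) for Fos, 0.24 (SE 0.38) for Arc and -0.06 (SE 0.30) for Nr4a1. No member of the immediate-early or effector lists passed when adjusted over the list alone. MAP kinase feedback regulators had a median log2 fold change of 0.08, with 8 of 11 above 0 (adjusted p = 0.0428, and 0.74 with an estimated correlation). The 3 interferon response genes had a median of -0.25, with 1 lower adjusted over the list alone (adjusted p = 0.0222, and 0.231 with an estimated correlation). Among the smallest p-values were those of 2210418O10Rik, Slc35f4, BC024978 and Slc31a2, each with an adjusted p of 1. Without DMSO replicate 2 the count was 1.

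**Figure D1:**
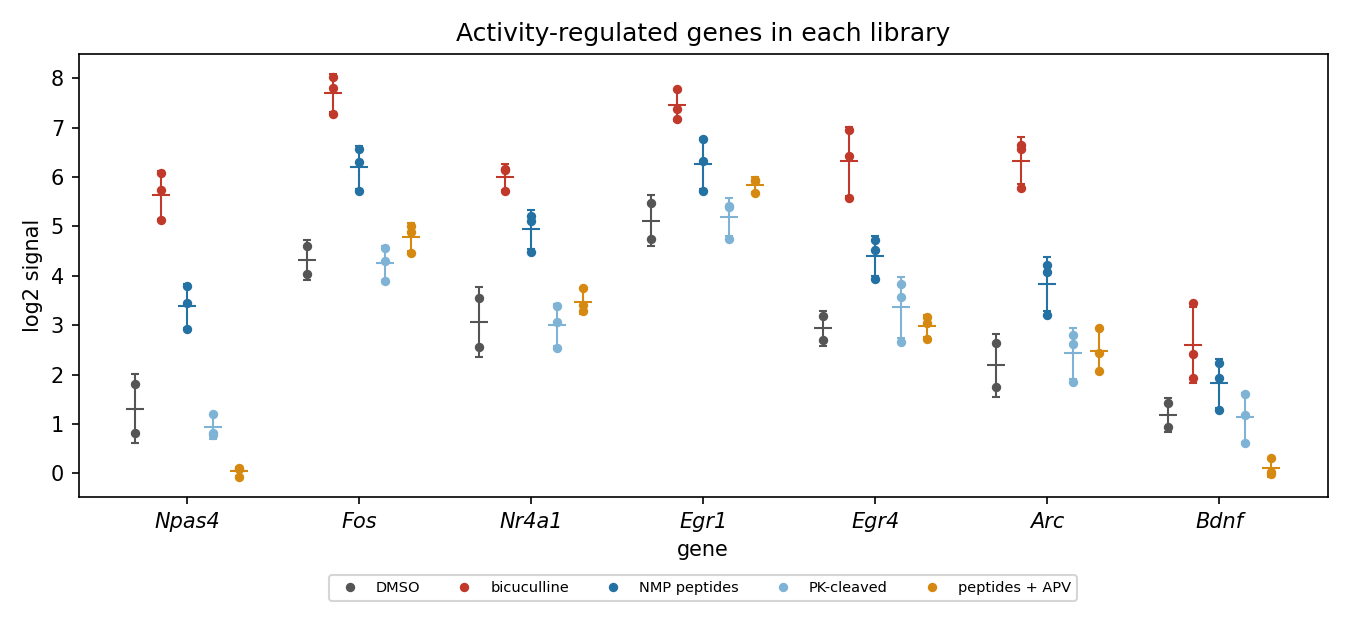
Log2 signal of 7 activity-regulated genes in the 14 libraries; points are libraries, horizontal marks group means and bars the SD. Npas4 lies between 5.12 and 6.08 with bicuculline, between 2.93 and 3.8 with NMP peptides and between 0.81 and 1.81 with DMSO.

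The peptide and bicuculline responses were compared directly. Bicuculline gave 19 genes higher and 0 lower than NMP peptides. Arc was 5.69-fold higher, Npas4 4.75-fold, Egr4 3.79-fold, Btg2 3.71-fold, Gadd45b 3.64-fold, Dusp1 2.85-fold and Fos 2.84-fold. Of the 20 immediate-early factors 7 were higher and of the 24 effectors 7 were higher (19 and 20 adjusted over the list alone). Both lists passed with an estimated correlation (adjusted p = 0.000771 and 0.00129). All 19 genes were among the 51 called for bicuculline against DMSO, although both comparisons use the bicuculline libraries. The count fell to 4 without filtering, 5 with only these groups in the fit, 4 without bicuculline replicate 1, 5 without NMP peptides replicate 3, 8 without NMP peptides replicate 1, 10 without the variance trend and 12 without bicuculline replicate 3. It rose to 34 without bicuculline replicate 2 and to 38 with array weights.

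Across genes, which are not independent replicates, fold changes against DMSO for bicuculline and for NMP peptides had a Pearson r of 0.783 and a Spearman rho of 0.751. Unchanged groups simulated against the shared DMSO libraries gave a mean r of 0.599 and rho of 0.569. The simulated libraries were independent, whereas real libraries of different groups deviated together (bicuculline replicate 2 and NMP peptides replicate 3 at r = 0.682 across genes), so the simulated values leave out any part that comes from shared deviations. The covariance was 0.0236, against 0.0114 simulated. Bicuculline against DMSO and NMP peptides against PK-cleaved NMP peptides, which share no library, had a Pearson r of 0.555 and a rho of 0.319. Of the 9 genes called in the latter, 8 were also called for bicuculline, where independent lists would share 0.042.

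The 51 genes raised by bicuculline were followed in comparisons that share no library with it. With NMP peptides against PK-cleaved peptides 50 of 51 lay above 0, with a median log2 fold change of 0.63 against 1.51 for bicuculline, and 37 were higher adjusted over these genes alone. The slope through the origin was 43.7% of the bicuculline change. The 51 genes were picked by their bicuculline values, which selection can raise, so this share may be too low. The control also differs, DMSO for bicuculline and PK-cleaved peptides for NMP peptides. With NMP peptides plus APV against PK-cleaved peptides 21 lay above 0 and 30 below, with a median of -0.14, and the slope was -1.5%. Adjusted over these genes alone, 0 were higher and 4 lower. Of these 51 genes, 1 passed there when adjusted over all genes: Nfil3, a transcriptional repressor, was lower (log2 fold change -0.60, SE 0.11, limma adjusted p = 0.0181). The slope near 0 sums changes in both directions. Fosb (0.772, SE 0.347) and Egr1 (0.656, SE 0.257) lay above 0, and Npas4 (-0.895, SE 0.274) and Rgs2 (-0.728, SE 0.18) below. No group with APV alone was analysed, so an effect of APV itself is part of these values.

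**Figure D2:**
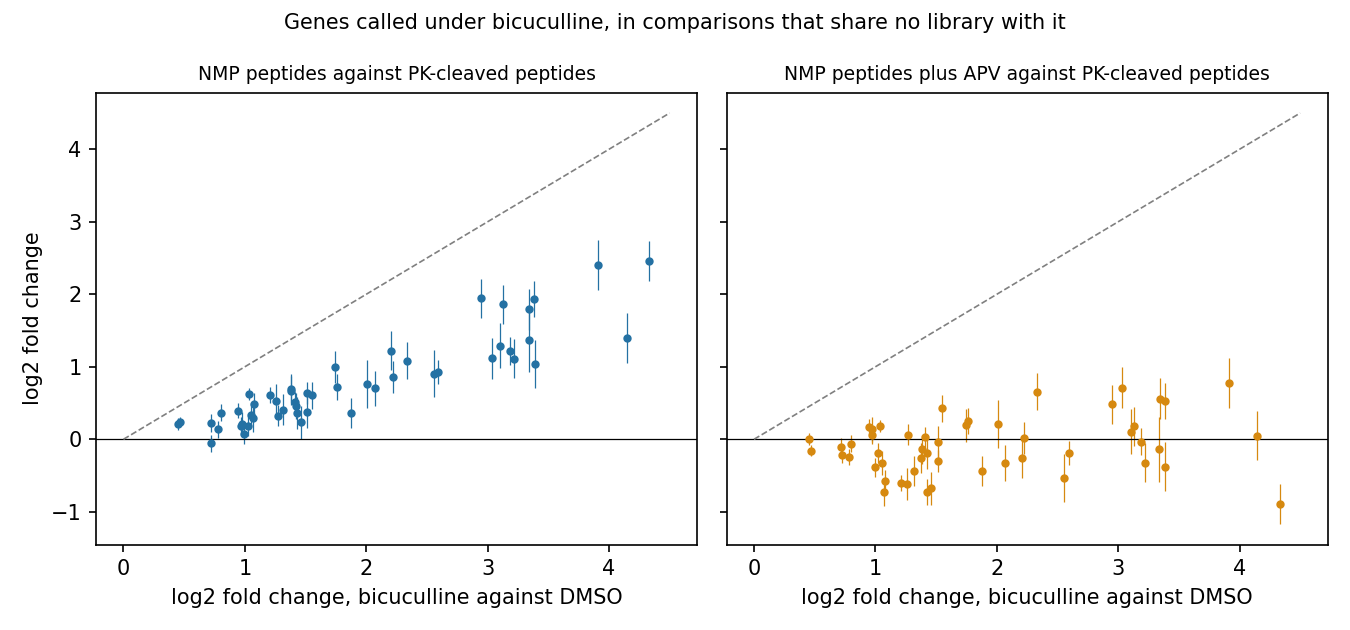
Log2 fold change of the 51 genes called under bicuculline (x axis, against DMSO) in NMP peptides (left) and NMP peptides plus APV (right), each against PK-cleaved peptides (y axis); bars are standard errors and the dashed line marks equal change. On the left 50 of the 51 points lie above 0, and on the right 21 do.

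NMP peptides alone were compared with the peptides given while NMDA receptors were blocked. Npas4 was 10.2-fold higher with NMP peptides alone than with NMP peptides plus APV, Nppc 4.31-fold and Bdnf 3.27-fold. Klf4 was 3.21-fold higher, Fosb 3.11-fold, Nr4a1 2.75-fold and Fos 2.67-fold. Arc (log2 fold change 1.34, SE 0.34, limma adjusted p = 0.0708), Egr4 (1.42, SE 0.33, adjusted p = 0.0534) and Egr1 (0.43, SE 0.26, adjusted p = 0.435) were not called. In all, 96 genes were higher and 60 lower with the peptides alone. Without the 4 libraries with the highest Gfap the split was 71 and 20. It was 72 and 29 without NMP peptides replicate 3, and 47 and 25 without replicate 1. It was 49 and 19 without APV replicate 1, 41 and 16 without APV replicate 3, and 78 and 42 with the replicate block. Some settings gave a more even split: 38 and 28 without NMP peptides replicate 2, and 53 and 37 without APV replicate 2. The stricter filter gave 52 and 45, median centring 92 and 66, fitting only these groups 101 and 70, and array weights 336 and 279. Of the 20 immediate-early factors 8 were higher (14 higher and 1 lower adjusted over the list alone), and of the 24 effectors 9 were higher (17 adjusted over the list alone), among them Vgf, Rgs2 and Gadd45b. The list calls were lost with an estimated correlation (adjusted p = 0.14 for each list). Of 18 genes of the unfolded protein and integrated stress response, Atf4 (1.77-fold) and Cebpb (1.86-fold) were higher, and this list had an adjusted p of 0.226 with an estimated correlation. The genes lower with the peptides alone were led by Gpr139, Slc44a5, Elk1 and Kctd4. Astrocyte markers had a median log2 fold change of -0.11 and oligodendrocyte lineage markers of -0.22 (adjusted p = 0.00435 and 0.0161 with the preset correlation, 0.14 for each with an estimated correlation). Excitatory neuron markers had a median of -0.24 (adjusted p = 0.0235, and 0.296 with an estimated correlation). No group with APV alone was analysed here, so an effect of APV itself is part of this comparison. Nppc had means of 2.01 with NMP peptides, 2.18 with DMSO and -0.10 with NMP peptides plus APV. The means of Bdnf were 1.82, 1.18 and 0.11. Of the 156 called genes, 56 were also called for NMP peptides plus APV against DMSO and 2 for NMP peptides against DMSO. Each of these comparisons shares 3 libraries with this one. The count was 97 with the stricter filter, 615 with array weights and 91 without the 4 libraries with the highest Gfap. Without NMP peptides replicates 1, 2 and 3 it was 72, 66 and 101, and without APV replicates 1, 2 and 3 it was 68, 90 and 57.

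Against DMSO, NMP peptides plus APV gave 19 genes higher and 49 lower, and 28 higher and 42 lower when each library was centred on its median. Nppc, which encodes C-type natriuretic peptide, was lower by a log2 fold change of -2.28 (SE 0.23), Cav1, the gene of caveolin 1, by -1.42 (SE 0.18), Opn3 by -1.39 (SE 0.13) and the vasopressin receptor gene Avpr1a by -1.30 (SE 0.16). Slc44a5 was 2.63-fold higher, Elk1, an ETS-family transcription factor gene, 2.11-fold, Hrk 1.84-fold and Prnp, the prion protein gene, 1.44-fold. Of the immediate-early factors and effectors 0 were called, and adjusted over the list alone 1 of 20 and 5 of 24 were lower. Npas4 was 0.04 ± 0.10 (SD, n = 3) against 1.31 ± 0.70 in DMSO (log2 fold change -1.27, SE 0.31, limma adjusted p = 0.0916), and Bdnf had a log2 fold change of -1.07 (SE 0.38, adjusted p = 0.305). The other index genes had values above 0, also not called: 0.73 (SE 0.29) for Egr1, 0.46 (SE 0.28) for Fos, 0.42 (SE 0.30) for Nr4a1, 0.29 (SE 0.38) for Arc and 0.05 (SE 0.37) for Egr4. Astrocyte markers had a median of 0.13 (adjusted p = 0.0077, and 0.394 with an estimated correlation). Fewer genes were called than in the main fit without the 4 libraries with the highest Gfap, which keeps 1 DMSO library. The count was 30 with the stricter filter, 32 with the replicate block and 5 with only these groups in the fit. It was 23 and 7 without DMSO replicates 2 and 3, and 31, 26 and 51 without APV replicates 1, 2 and 3.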

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

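Counts of called genes depended on the settings, and causes were not tested. For NMP peptides against DMSO (2 genes), the count was 0 without a filter, with the stricter filter, with the replicate block, with only these groups, without the variance trend and with array weights, and 6 with median centring. With only the compared groups it was 27 for bicuculline against DMSO, 5 for NMP peptides plus APV against DMSO and 5 for bicuculline against NMP peptides. No filter gave 4 for NMP peptides against PK-cleaved peptides and 4 for bicuculline against NMP peptides; the stricter filter gave 30 for NMP peptides plus APV against DMSO and 97 for NMP peptides against NMP peptides plus APV. No variance trend gave 10, and array weights 38, for bicuculline against NMP peptides; array weights gave 615 for NMP peptides against NMP peptides plus APV. Median centring moved no other count by over 1.5 times.

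Leaving out 1 library gave 30 to 55 genes for bicuculline against DMSO, 0 to 10 for NMP peptides, 0 to 1 for PK-cleaved peptides and 7 to 51 for NMP peptides plus APV, each against DMSO. It gave 1 to 11 for NMP peptides against PK-cleaved peptides, 57 to 101 against NMP peptides plus APV and 4 to 34 for bicuculline against NMP peptides. Where DMSO keeps 1 library, it is assumed to vary like the others. Of 594 tests of a named called gene with 1 library left out, 364 stayed past the threshold, 230 did not and 0 reversed.

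The next alternatives were chosen after seeing the data. The 4 libraries with the highest Gfap are 1 each of DMSO, bicuculline, NMP peptides and PK-cleaved NMP peptides. Leaving them out keeps 1 DMSO library, which is again assumed to vary like the others. A change in a result there may come from the smaller number of libraries alone. Without the 4 libraries with the highest Gfap the count was 9 for NMP peptides and 16 for NMP peptides plus APV against DMSO, and 91 for NMP peptides against NMP peptides plus APV; the effector list was then lower in NMP peptides plus APV against DMSO at the preset correlation (adjusted p = 0.0209) and did not pass with an estimated correlation (adjusted p = 0.908). The immediate-early list in NMP peptides against DMSO then had an adjusted p of 0.0634 with an estimated correlation. With 2 residual principal components as covariates the counts were 107, 28, 878, 23, 1851 and 56 for bicuculline, NMP peptides and NMP peptides plus APV against DMSO, NMP peptides against PK-cleaved peptides and against NMP peptides plus APV, and bicuculline against NMP peptides. These covariates were taken from the same residuals that set the spread, so these counts are too high.

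The replicate block gave 0 calls for NMP peptides and 32 for NMP peptides plus APV against DMSO. Over all groups the numbers did not pair the libraries: deviations of the 26 same-numbered pairs correlated at -0.48 to 0.613, and 6 of 14 libraries correlated best with their own number. Libraries of different groups that deviated together often had different numbers, so this block did not follow them. The numbers did pair NMP peptides with PK-cleaved peptides. A replicate block over these groups alone, chosen after seeing the data, gave 11 genes with all libraries in the fit and 25 with only these groups, and changed no call of the activity lists. The correlation of bicuculline and peptide fold changes was 0.631 without a filter and 0.555 with no shared library. The effector list had an adjusted p of 0.0595 (estimated correlation) and 0.144 (fry) for NMP peptides against DMSO, and 0.0596 and 0.158 against PK-cleaved peptides; against NMP peptides plus APV both activity lists had 0.14 with an estimated correlation.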

Other observations

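The gene list tests in this part were fixed before the data were examined. The tests on the genes that differed with NMP peptides plus APV, and the genes and libraries singled out here, were chosen after the results were seen. In bicuculline against DMSO, proteasome subunits had a median log2 fold change of 0.01 (36 genes), ionotropic glutamate receptor subunits -0.06 (13 genes), GABA-A receptor subunits -0.05 (12 genes) and excitatory neuron markers -0.04 (12 genes), each with 0 called genes. Inhibitory neuron markers had a median of 0.06 there (13 genes, adjusted p = 0.0369, and 0.114 with an estimated correlation). Oligodendrocyte lineage markers had a median of -0.16 in NMP peptides against DMSO, with 0 of 8 above 0 (adjusted p = 0.0343, and 0.233 with an estimated correlation). Proteasome subunits had a median of 0.02 in NMP peptides against DMSO (adjusted p = 0.0271, and 0.507 with an estimated correlation) and of 0.09 against NMP peptides plus APV, with 32 of 36 above 0 and 0 called (adjusted p = 0.00086, and 0.268 with an estimated correlation). In the latter comparison ionotropic glutamate receptor subunits had a median of -0.06, interferon response genes of -0.34 and proliferating progenitor markers of -0.25, with 0 called (adjusted p = 0.0161 for each, and 0.395, 0.14 and 0.195 with an estimated correlation). MAP kinase feedback regulators had medians of 0.15, 0.07, 0.32 and 0.26 in NMP peptides against DMSO, against PK-cleaved peptides and against NMP peptides plus APV, and in bicuculline against NMP peptides. Their adjusted p was 7.41e-07, 0.000667, 0.000624 and 4.11e-18, and 0.106, 0.372, 0.195 and 0.00548 with an estimated correlation. Heat shock chaperones had a median of 0.04 in bicuculline against NMP peptides, with 1 of 13 called (adjusted p = 0.00954, and 0.186 with an estimated correlation). Cholesterol synthesis genes had medians of -0.13 with NMP peptides, -0.12 with bicuculline and -0.09 with PK-cleaved NMP peptides against the same DMSO libraries, with 0 of 17 called in each (adjusted p = 0.00118, 0.022 and 0.051, and 0.504, 0.655 and 0.74 with an estimated correlation). Unfolded protein and integrated stress response genes had medians of 0.25 with bicuculline, 0.21 with NMP peptides and 0.07 with PK-cleaved NMP peptides against those libraries, with 0 of 18 called in each (adjusted p = 3.81e-07, 1.52e-06 and 0.0158, and 0.326, 0.389 and 0.74 with an estimated correlation). In NMP peptides against PK-cleaved peptides the median was 0.11 (adjusted p = 0.0138, and 0.903 with an estimated correlation). Members of this list varied between the DMSO libraries, with an SD of 1.13 for Ddit3 and 0.96 for Chac1 (n = 2). Ptgs2, which encodes the inducible cyclooxygenase, fell below the filter; without a filter it was higher with bicuculline (log2 fold change 3.70, SE 0.50, limma adjusted p = 0.00685). Txnip, which encodes a thioredoxin-binding protein, lay between 2.34 and 2.89 with NMP peptides and between 3.64 and 4.73 with DMSO but was not called, and its relative Arrdc4 had means of 4.18 and 4.28.

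Libraries of different groups deviated together. Gfap, an astrocyte filament gene, lay between 3.97 and 4.18 in 1 library each of DMSO, bicuculline, NMP peptides and PK-cleaved NMP peptides, and between 2.15 and 3.47 in the others. Within-group deviations of those 4 libraries correlated across genes at 0.413 to 0.682. Other libraries did so too, but these correlations are not separate observations. Deviations sum to 0 within a group, and those of the 2 DMSO libraries are exact opposites. Where 1 library per group deviates together, part of the correlation among the others follows from this. DMSO replicate 3 was closest to bicuculline replicate 1 (0.478). Bicuculline replicate 1 and NMP peptides replicate 2 were closest to PK-cleaved NMP peptides replicate 2 (0.528 and 0.499). Bicuculline replicate 3 was closest to NMP peptides replicate 1 (0.466), itself closest to PK-cleaved NMP peptides replicate 1 (0.51). The main fit treats libraries as independent, and these sets were not fitted as blocks.

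The genes lower with NMP peptides plus APV than with DMSO had a median log2 fold change of -0.63 over 49 genes. Excitatory and inhibitory neuron markers had medians of 0.09 and -0.096 there, above the upper quartile of the 49 genes (-0.53). This cannot decide on a loss of neurons as a whole. The 49 genes were picked as lower in this same comparison, which fixes a low quartile. Quantile normalisation would also hide a change in total RNA. A reversed response to network activity was not seen for these genes as a set and stays open for single genes. In bicuculline against PK-cleaved peptides, with no shared library, the 49 genes had a median of 0.021 (quartiles -0.041 and 0.086), with 27 above 0. The 19 higher genes had a median of -0.01 there, with 9 above 0. Another make-up of the cultures also stays open: astrocyte markers passed with the preset correlation (adjusted p = 0.0077) and not with an estimated one (0.394). No batch is given in the labels, and the highest correlation of deviations between an APV library and a library of another group, 0.371, does not decide whether these libraries were made apart. APV itself, without peptides, was untested.

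With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave as many calls as any in 1 of 10 for each comparison: 9 genes for NMP peptides against PK-cleaved NMP peptides, 156 against NMP peptides plus APV and 19 for bicuculline against NMP peptides. The highest of the other splits gave 0 in each. For NMP peptides against PK-cleaved peptides, whose numbers pair the libraries, 4 splits part all 3 pairs. With the block the real one gave 11 genes and the highest of the others 0. All of these other splits mix libraries of both groups, so a real difference enters the spread and lowers the calls. Their 0 calls therefore decide nothing about chance.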
